A study of Mus musculus with 6 samples.

How the data were processed

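Total RNA from 6 mouse hearts, 3 of Ppif-/- and 3 of WT mice aged 8 weeks, was hybridised to 1 Affymetrix Gene 1.0 ST array each. Per the labels' protocols, hearts were removed quickly and kept in a preservative at 4 degrees before extraction with a fibrous tissue kit, and biotin-labelled sense-strand cDNA was hybridised. Per the labels, the Ppif-/- mice were backcrossed to C57BL/6 from a Sv129 background. How many backcrosses were made, whether WT mice were littermates, and the hour at which hearts were collected are not given in the sources used here.

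The deposited values are log2 expression per probe set, and per the submitters' processing notes they were made with RMA, a method that corrects background, normalises between arrays and summarises the probes of a probe set. The RMA software, its version and any filter are not given in the sources used here. RMA compresses differences at low signal, which can understate the folds of dim transcripts, and values near the floor carry little information. No detection calls, scan dates or batches were given, so no batch could be tested. The values, from 1.91 to 14.63 with none missing, were used as deposited. No array pair held identical values, and 0 columns lacked a sample.

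Probe sets were named through the platform annotation, with symbols updated by Entrez identifier to a gene table of the mouse assembly GRCm38.p6. Of 35557 probe sets, 21789 carried 1 gene symbol, 1621 several and 12147 none in that annotation, and 21698 of those with 1 symbol matched the gene table. The 23410 probe sets with at least 1 symbol were tested, and genes were named only from probe sets with exactly 1. What part of Ppif its probe set reads was not given. The gene table served for names and for the order of genes along chromosomes, and no coordinates are printed, since the build behind the array files was not stated.

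Ppif-/- and WT hearts were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, without covariates), with Benjamini-Hochberg adjustment and a threshold of 0.05. A looser count took an unadjusted p under 0.01 with an absolute log2 difference of 0.5 or more. Differences are Ppif-/- minus WT on the log2 scale with the standard error of the fit, and folds are 2 to that power. An exact permutation test of 3 against 3 hearts cannot go below 0.1 for a single gene, so only moderated tests are reported per gene.

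Gene lists were fixed before the data were examined: 24 lists of pathways and 13 of cell type markers, holding 692 genes. Each gene was represented by its probe set with the highest mean over all arrays; 637 listed genes were measured by a probe set with 1 symbol, and the others were not analysed here. Lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the pathway lists and separately over the cell type lists. Of these, 6 pathway lists and 3 cell type lists passed, 0 and 0 passed with the correlation estimated from the data, and at an unadjusted p under 0.05 the estimated correlation left 2 and 0. With fry, which asks whether the genes of a list move on balance one way, 2 pathway lists passed (immediate early genes and clock) and 0 cell type lists, with 8 and 7 at an unadjusted p under 0.05. With 3 arrays per group the estimated correlation is itself uncertain.

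Genes were named by a rule set before the data were examined. It took Ppif, the 12 higher and 12 lower probe sets with the smallest p among those past the threshold, and in each list the members past the threshold over the list alone, at most 4 by smallest p, or the 2 with the smallest p where fewer than 2 passed. It also took Nnt, the 10 measured neighbours on each side of Ppif, since linked genes may stem from the Sv129 background, and sex-linked genes. The neighbours of Ppif are given as counts, and one further gene that the rule takes is not reported here. Genes outside the rule are said to have been chosen after their values were seen.

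The alternatives tried were the replicate number as a block, a filter on low values, all probe sets, 1 probe set per gene, quantile normalisation, centring on array medians, eBayes with a trend or robust, array weights, other set tests, and leaving out each heart in turn. A fit on probe sets with exactly 1 symbol was added after the data were seen. The procedure was tested on simulated arrays of the Ppif-/- against WT comparison, 23410 probe sets with 200 changed. It recovered 50% of changes of log2 size 0.5, 88% of size 1 and 100% of sizes 2 and 3, with 5.59% false calls among the calls, and made 0 calls and found 0 lists when nothing was changed. A list shifted by 0.3 was the 1 list found. The simulated probe sets varied independently of each other, while the correlation estimated in the real data reached 0.453, for the sex-linked list. The 0 lists therefore do not show how the set test behaves when genes vary together.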

Results

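Gene expression was measured in whole hearts of mice aged 8 weeks on Affymetrix Gene 1.0 ST arrays, which read each transcript through many probes summarised as a probe set. The 6 arrays held 3 hearts from Ppif-/- mice, which lack cyclophilin D throughout the body, and 3 hearts from wild-type (WT) mice, numbered in the labels as separate hearts. Cyclophilin D is a peptidyl-prolyl isomerase of the mitochondrial matrix that promotes opening of the permeability transition pore. The series gives as its purpose to find transcripts that differ ahead of cardiac dysfunction, and cardiac function was not analysed here. Each array gave log2 values for 35557 probe sets, with array medians between 6.03 and 6.11. Across probe sets, which are not independent replicates, pairs of arrays correlated at 0.995 to 0.997 within a genotype and at 0.991 to 0.995 between genotypes, and the principal component with the highest variance (44.4%) separated the genotypes. The number of arrays limits the precision of every value below.

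Ppif itself had the largest decrease among probe sets with a gene symbol, at 6.23 ± 0.22 in Ppif-/- hearts and 11.40 ± 0.11 in WT hearts (log2, mean ± SD, n = 3 each). The difference of -5.17 ± 0.12 (SE) corresponded to a 36.0-fold lower level (limma adjusted p = 2.97e-06), with each Ppif-/- heart below each WT heart. Among the 20 measured genes that lie nearest to Ppif on its chromosome, 10 on each side, 0 passed the threshold in limma. The smallest unadjusted limma p among them was 0.0317, and the largest absolute difference was 0.235. Nnt, a mitochondrial transhydrogenase that carries a deletion in the C57BL/6J substrain, differed by -0.22 ± 0.06 and did not pass (adjusted p = 0.18), with values of 12.80 in Ppif-/- and 13.03 in WT hearts. Of the 4 measured sex-linked genes, the Y-linked demethylase Kdm5d was higher by 0.49 ± 0.08 (adjusted p = 0.0348) and Uty (0.15), Eif2s3y (0.08) and Xist (0.15) did not pass. The call of Kdm5d was lost without any 1 heart (adjusted p = 0.0654 to 0.123). The sex-linked list passed the set test (adjusted p = 0.0319), but not with an estimated correlation (adjusted p = 0.707), with array weights (0.0823), or without Ppif-/- heart 1, WT heart 2 or WT heart 3 (0.134, 0.0721 and 0.107). That list pools Xist with Y-linked genes, so its test does not speak to sex. Every heart had low Xist (3.66 to 4.29) and high Y-linked Eif2s3y (9.32 to 9.61), the pattern of male hearts in both genotypes.

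In total, 254 of the 23410 probe sets with a gene symbol passed an adjusted p of 0.05, of which 146 were higher and 108 lower in Ppif-/- hearts. The 242 of them that carried exactly 1 symbol stood for 232 genes. A change of at least 2-fold was found for 71 probe sets, 50 higher and 21 lower. All 254 had every Ppif-/- heart on one side of every WT heart, as did 19.8% of all tested probe sets, where chance alone gives 10%. A looser count, an unadjusted p under 0.01 with a log2 difference of at least 0.5, took 396 probe sets, 223 higher and 173 lower. The adjusted count was 171 without Ppif-/- heart 1, 139 without Ppif-/- heart 2 and 131 without Ppif-/- heart 3. It was 149 without WT heart 1, 158 without WT heart 2 and 147 without WT heart 3. With the replicate number as a block the count was 160. It was 405 on the brighter probe sets alone, 131 when all probe sets of the table were tested, 453 with a variance trend and 386 with array weights, and 0 calls changed sign in any of these fits. Among the genes named by the rule, testing all probe sets ended the calls of Pdgfra, Cd68, Tagln, Nqo1, Per1, Bhlhe41, Ankrd1, Ifit2, Nfe2l2, Slc25a31, Micu3 and Kdm5d (adjusted p = 0.0627 to 0.134).

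The higher transcripts with the smallest p-values included enzymes of lipid metabolism and immediate early transcription factors. Plaat1, a phospholipase and acyltransferase, rose from 5.52 ± 0.17 in WT to 8.90 ± 0.04 in Ppif-/- hearts (10.4-fold, adjusted p = 6.2e-06). Elovl7, an elongase of very long chain fatty acids, was 7.28-fold higher (2.86 ± 0.11) and Hsd17b7, an enzyme of cholesterol synthesis, was 4.40-fold higher (2.14 ± 0.08). Pttg1, which encodes securin, rose by 3.22 ± 0.12 and Nedd1, a centrosomal protein that recruits gamma-tubulin, by 1.40 ± 0.07. The actin regulator Cyfip2 was higher by 2.51 ± 0.10, the cytokine Il15 by 2.46 ± 0.13 and the R-spondin receptor Lgr6 by 2.09 ± 0.12. One probe set of the snoRNA host gene Gas5 was higher by 1.77 ± 0.11, and the other 3 Gas5 probe sets did not pass. Egr1 (2.48 ± 0.10), Egr2 (2.48 ± 0.15) and Nr4a1 (2.15 ± 0.10), transcription factors induced within minutes of a stimulus, completed the 12 higher transcripts named by rank. All 12 had an adjusted p of at most 0.000406 and were higher in 3 of 3 Ppif-/- hearts.

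Next to Ppif, the lower transcripts with the smallest p-values spanned amino acid breakdown, immunity, contraction and ion transport. Hal, histidine ammonia-lyase, fell from 7.34 ± 0.05 in WT to 4.99 ± 0.15 in Ppif-/- hearts (5.11-fold lower, adjusted p = 2.79e-05). The interferon-inducible genes Gbp2b and Ifi202b differed by -2.53 ± 0.12 and -0.98 ± 0.08, the latter from a low WT level of 4.54. Myl1, a myosin light chain of fast skeletal muscle, differed by -1.44 ± 0.10, and Tac1, the precursor of substance P, by -1.12 ± 0.09 from a low WT level of 5.06. The lysosomal protease Ctsf fell by 1.02 ± 0.07, Ttc38 by 1.20 ± 0.09 and the transcript 4833420G17Rik by 1.18 ± 0.10. Kcnj11, the pore subunit of the ATP-sensitive potassium channel, was 8.97 ± 0.05 in Ppif-/- and 9.72 ± 0.05 in WT hearts (-0.75 ± 0.07, adjusted p = 0.00233). Acp1, a protein tyrosine phosphatase, gave no single direction: 1 probe set differed by -1.83 ± 0.09, while the other 4 were higher by 0.55 to 0.71, and all 5 passed. Which transcripts each of these probe sets reads was not resolved.

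**Figure D1:**
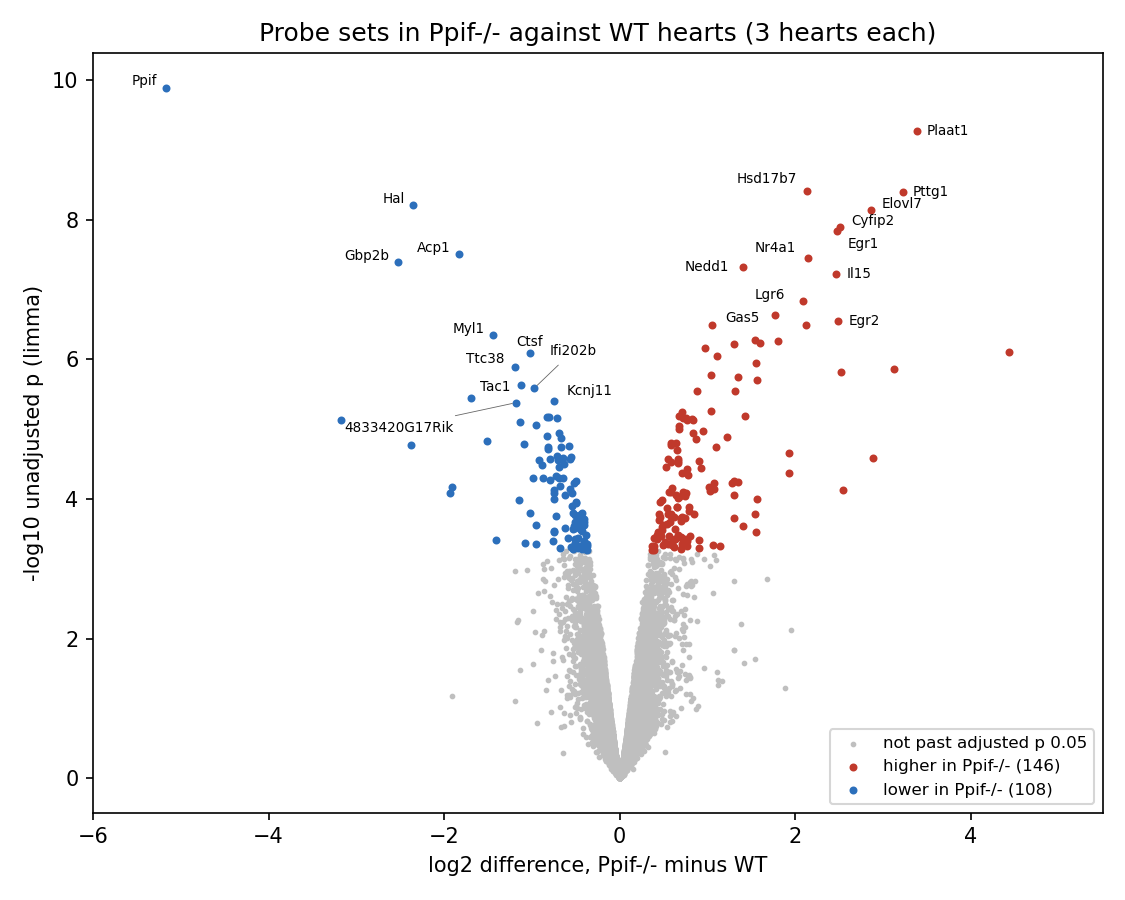
Log2 difference (Ppif-/- minus WT, x axis) against -log10 of the unadjusted limma p (y axis) for the 23410 probe sets with a gene symbol, each point 1 probe set over 3 hearts per genotype. The 146 higher and 108 lower probe sets past an adjusted p of 0.05 are coloured, and Ppif lies apart at -5.17.

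Immediate early genes were higher in Ppif-/- hearts. Of 25 measured members, 9 rose with adjustment over all genes tested and 17 when adjusted over the list alone, with 0 lower by either count, and the median difference was 0.58. Beside Egr1, Egr2 and Nr4a1, the MAP kinase phosphatase Dusp1 was higher by 0.95 ± 0.10 (adjusted p = 0.00421). Fos differed by 1.67 ± 0.35 and passed over the list alone but not over all genes (adjusted p = 0.0795), with a wide spread between the Ppif-/- hearts, and was chosen after its value was seen. Transcripts of the circadian clock differed as well. Of 17 measured members, 6 were higher and 1 lower over all genes, and 10 were higher and 2 lower when adjusted over the list alone. Dbp, an output gene of the clock, was 2.96-fold higher (1.57 ± 0.13, adjusted p = 0.00137), Bhlhe40 was higher by 0.77 ± 0.07, the repressor Per1 by 1.07 ± 0.14 and Bhlhe41 by 0.65 ± 0.09. Arntl, which encodes the activator BMAL1, was the 1 lower member over all genes (-1.41 ± 0.24, adjusted p = 0.0418) and was chosen after its value was seen. Both lists passed the set test (adjusted p = 3.05e-19 for immediate early genes and 9.18e-06 for the clock), but neither did with an estimated correlation (adjusted p = 0.17 for each). The call of Per1 was lost without WT heart 1 (adjusted p = 0.0511), and that of Bhlhe41 without Ppif-/- heart 1 or 3 or any single WT heart (adjusted p = 0.0507 to 0.0841).

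**Figure D2:**
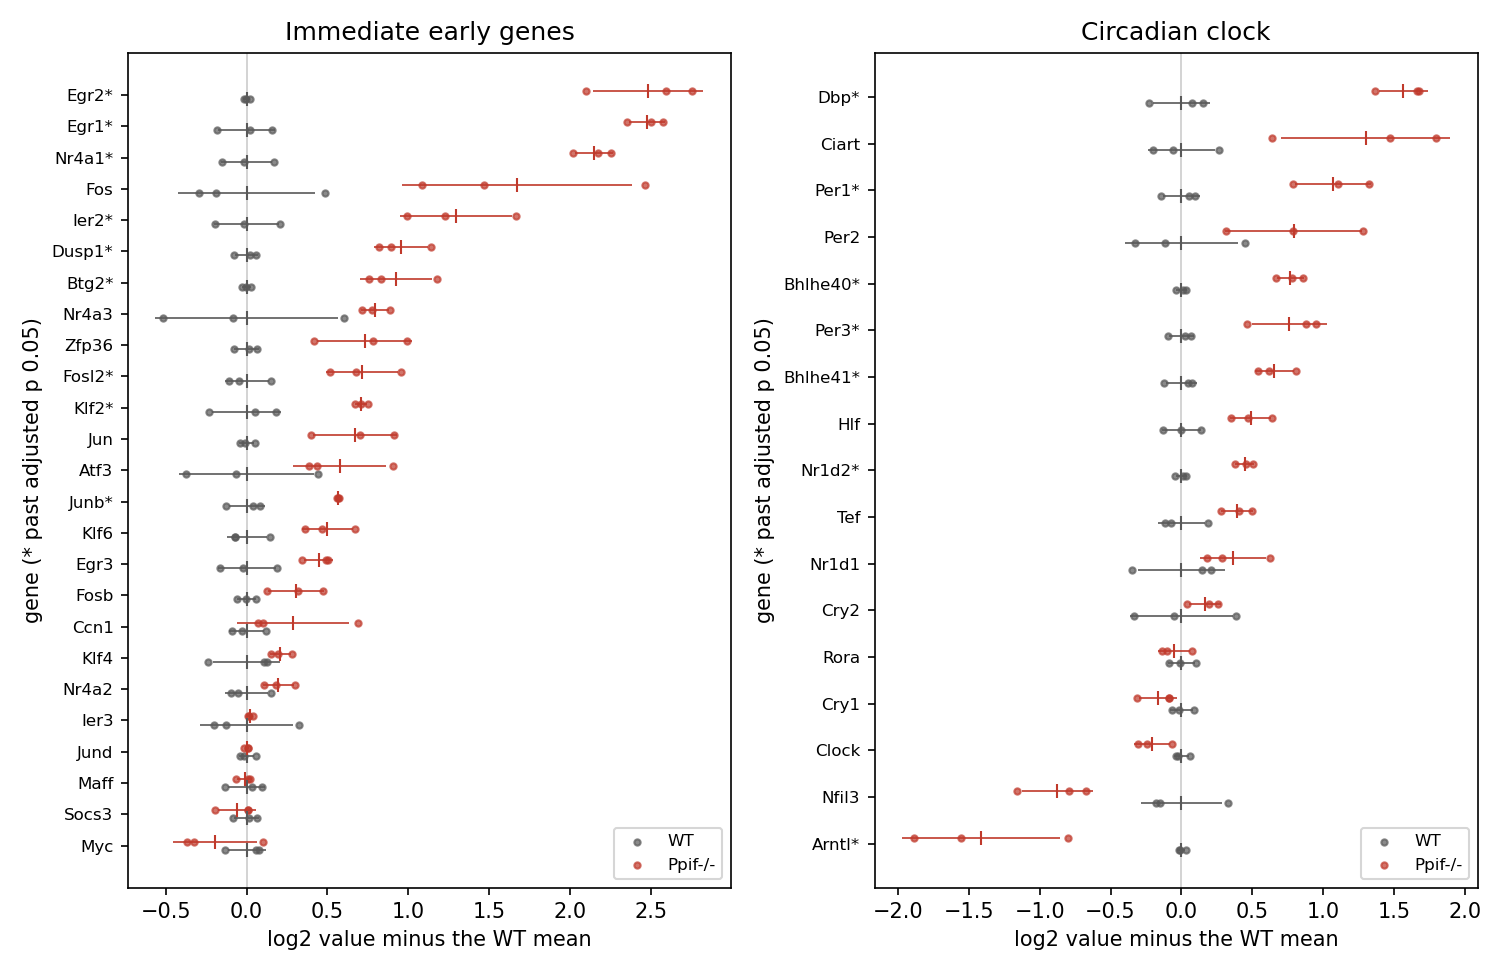
Log2 value of each heart minus the WT mean (x axis) for the measured immediate early genes (left, 25 genes) and clock genes (right, 17 genes), with WT hearts in grey, Ppif-/- hearts in red, a tick at each mean and a bar of 1 SD (n = 3). Egr2, Egr1 and Nr4a1 lie more than 2 log2 units above WT, and Arntl lies at -1.41.

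Interferon-induced genes were higher in part. Of 21 measured members, 1 passed over all genes, the antiviral gene Ifit2 (0.76 ± 0.13, adjusted p = 0.0413), and 10 were higher when adjusted over the list alone. These included Ifit1 at 0.86 ± 0.18, the MHC class I light chain B2m at 0.49 ± 0.10 and the tetherin gene Bst2 at 0.76 ± 0.16. The list passed the set test (adjusted p = 1.26e-07), but not with an estimated correlation (adjusted p = 0.707). The call of Ifit2 was lost without each of the hearts but Ppif-/- heart 3 (adjusted p = 0.0668 to 0.137), and the interferon-inducible genes Gbp2b and Ifi202b, outside the list, lay in the other direction.

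Among the lists of fuel breakdown, genes of glycolysis and of branched-chain amino acid breakdown passed over all genes, 1 and 2 of them. Pfkp, the platelet isoform of the glycolytic enzyme phosphofructokinase, rose from 9.45 ± 0.11 to 10.75 ± 0.11 (2.46-fold, adjusted p = 0.000615). Bcat2, the mitochondrial aminotransferase that starts the breakdown of branched-chain amino acids, was 2.07-fold higher (1.05 ± 0.07, adjusted p = 0.000425). Mccc1, a carboxylase subunit of leucine breakdown, was 1.96-fold higher (0.97 ± 0.07, adjusted p = 0.000669). When adjusted over the list alone, 2 glycolytic genes were higher and 1 lower of 22, and 3 genes of ketone and branched-chain amino acid breakdown were higher and 2 lower of 21. Beside Pfkp, the glycolytic ones were the regulatory enzyme Pfkfb3 (0.39 ± 0.09) and the mutase Pgam1 (-0.28 ± 0.07). In the amino acid list, Dbt, a subunit of the branched-chain ketoacid dehydrogenase, was at -0.38 ± 0.07 and the mutase Mmut at 0.26 ± 0.06. Neither list passed as a set (adjusted p = 0.869 and 0.954), and in the latter list the median (-0.04) and the test pointed lower while the mean was 0.04. In glycolysis the median (-0.01) was likewise opposite in sign to the mean (0.04) and the test.

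For fatty acid oxidation, 0 of 22 measured genes passed in limma over all genes or over the list alone, with 2 lower at an unadjusted p under 0.05, and the list did not pass (adjusted p = 0.0688, median -0.04). It did lie lower without Ppif-/- heart 2 or WT heart 1 (adjusted p = 0.0331 and 0.0428) and with a variance trend (0.0105). The 2 with the smallest p were Cpt2, the inner membrane carnitine palmitoyltransferase, at -0.22, and Acad10 at -0.21. For fatty acid uptake and lipid storage, 0 of 20 genes passed by either count and 6 were lower at an unadjusted p under 0.05, with the lipid droplet gene Plin4 at -0.43 and the triglyceride synthesis gene Dgat2 at -0.37. That list lay lower as a set (median -0.10, adjusted p = 0.0206), but not with an estimated correlation (adjusted p = 0.707) without WT heart 2 (0.0856), with array weights (0.0507) or on the brighter probe sets (0.0502). Of 18 PPAR alpha targets, 0 passed in limma over all genes, 3 were lower at an unadjusted p under 0.05, and 1 was lower when adjusted over the list alone. This was Pdk4, the kinase that shuts off pyruvate dehydrogenase, at 11.41 ± 0.20 in Ppif-/- and 12.61 ± 0.52 in WT hearts (-1.20 ± 0.24, adjusted p = 0.0709). The target with the next smallest p was the decarboxylase Mlycd at -0.31, and the list did not pass (adjusted p = 0.106) unless Ppif-/- heart 2 or WT heart 1 was left out (0.0389 and 0.0428). Of 30 genes of pyruvate oxidation and the TCA cycle, 0 passed over all genes in limma and 5 had an unadjusted p under 0.05. When adjusted over that list alone, 1 was higher, the pyruvate dehydrogenase phosphatase Pdp1 (0.27 ± 0.06), and 4 were lower, among them Pdk4, Pdhx (-0.31 ± 0.07) and Sdhc (-0.28 ± 0.07). That list did not pass the set test (adjusted p = 0.363).

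Of 35 complex I, 23 complex III and IV and 17 ATP synthase genes, 0 passed in limma over all genes or over their list alone, and 1, 0 and 2 had an unadjusted p under 0.05. The list medians were 0.03, 0.04 and 0.04, and the lists did not pass (adjusted p = 0.142, 0.142 and 0.0606). Leaving out 1 heart brought complex I past the threshold without WT heart 1 (0.0342), complexes III and IV without Ppif-/- heart 3 (0.0393) and ATP synthase without Ppif-/- heart 3 or WT heart 1 (0.0162 and 0.0395). The ATP synthase list also passed on the brighter probe sets (0.0329) and with a variance trend (0.00891). The members with the smallest p were Ndufa2 (0.15) and Ndufa5 (0.14) in complex I, Cox8a (0.17) and Cox4i2 (0.16) in complex IV, and the ATPase inhibitor Atpif1 (0.31) and Atp5md (0.19) at ATP synthase.

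**Figure D3:**
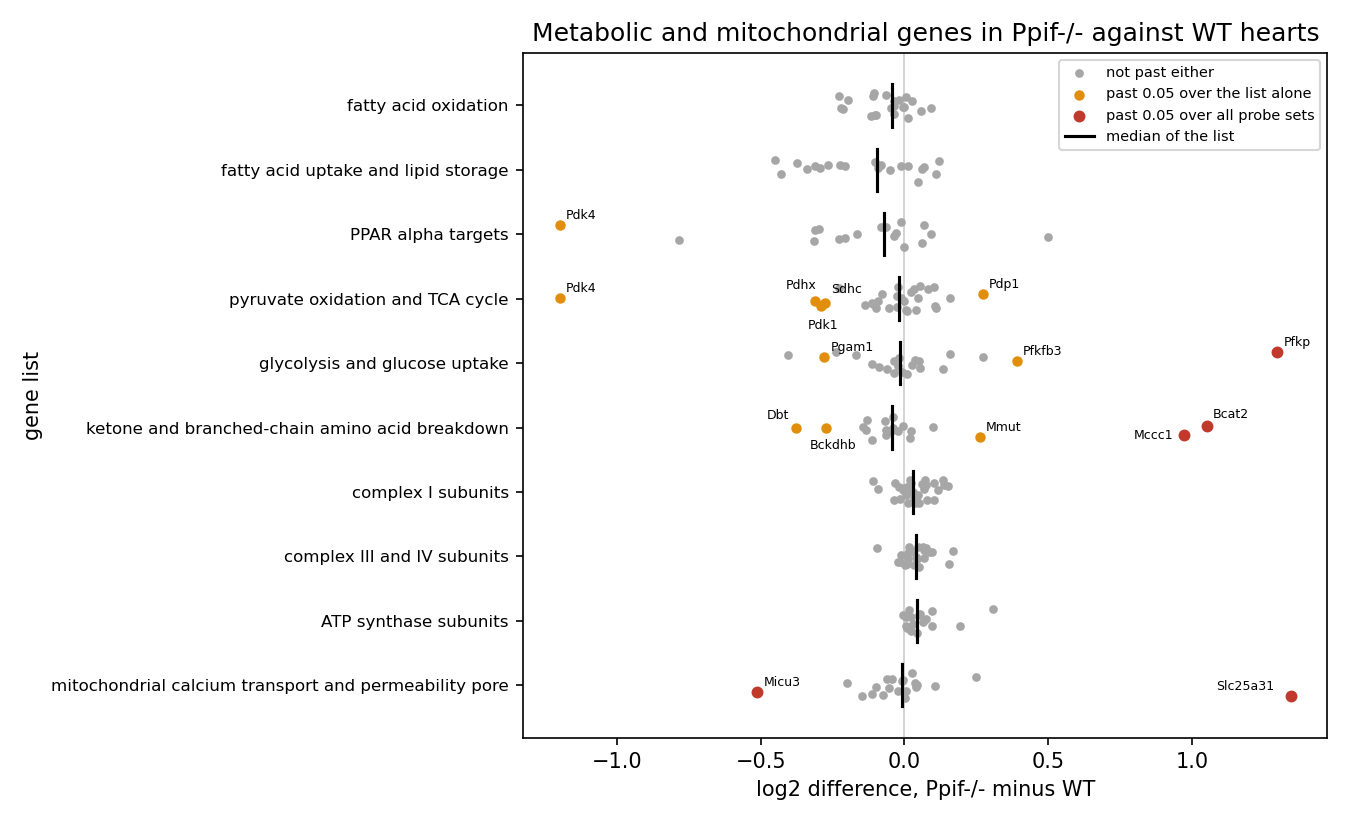
Log2 difference (Ppif-/- minus WT, x axis) of each measured gene in 10 metabolic and mitochondrial lists (y axis, points spread vertically for sight), with the list median as a black bar. Pfkp, Bcat2, Mccc1, Slc25a31 and Micu3 passed over all probe sets tested (red), further genes passed over their list alone (orange), and the medians lie between -0.10 and 0.04.

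Of 21 genes of mitochondrial calcium transport and the permeability pore, 1 was higher and 1 lower by either count. Slc25a31, an adenine nucleotide translocase isoform best known from testis, rose from a low 4.53 ± 0.06 to 5.87 ± 0.38 (adjusted p = 0.0122), and Micu3, a regulator of the calcium uniporter, differed by -0.51 ± 0.09 (adjusted p = 0.0416). Among 21 other cyclophilins and FKBPs, 0 passed over all genes in limma and 5 were higher at an unadjusted p under 0.05. Ppwd1, a cyclophilin with WD40 repeats, was higher over the list alone (0.57 ± 0.10) and Ppil1 stood at 0.46. That list lay higher as a set (median 0.07, adjusted p = 0.0448), but not with an estimated correlation (adjusted p = 0.872). The set call was also lost without Ppif-/- heart 1, WT heart 2 or WT heart 3 (adjusted p = 0.0744 to 0.379), with arrays centred on their medians (0.0524) and with array weights (0.11).

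By both counts, 1 member was higher and 0 lower in each of 3 further lists. Among 21 regulators of mitochondrial biogenesis this was Nfe2l2, a regulator of antioxidant genes (0.54 ± 0.08, adjusted p = 0.0216), with Ppargc1b at 0.23. Among 27 antioxidant genes it was the quinone reductase Nqo1 (0.37 ± 0.07, adjusted p = 0.0493), with Nnt next by p. Among 24 mitochondrial chaperone and stress genes it was Asns, asparagine synthetase (1.04 ± 0.10, adjusted p = 0.00305), with the serine synthesis gene Phgdh at -0.20. Of 27 apoptosis and mitophagy genes, 0 passed over all genes in limma, 4 had an unadjusted p under 0.05, and Map1lc3a was higher over the list alone (0.36 ± 0.07), with Bcl2 at 0.46. None of the lists on biogenesis, antioxidants, chaperones, apoptosis or the pore passed as a set (adjusted p = 0.989, 0.157, 0.989, 0.989 and 0.954), except antioxidants, lower without WT heart 1 (0.0281), and the mean and median of biogenesis and of the pore had opposite signs. The apoptosis test pointed higher while its mean and median were below 0, and the chaperone mean alone was above 0. Without 1 heart, the calls of Nqo1 and Micu3 were lost whichever it was (adjusted p = 0.0998 to 0.176 and 0.0661 to 0.135; Nqo1 also with centred arrays or robust eBayes, 0.0546 and 0.0514), that of Nfe2l2 unless it was Ppif-/- heart 1 (0.0517 to 0.0959), and that of Slc25a31 for Ppif-/- heart 3, WT heart 2 or WT heart 3 (0.0538 to 0.0684).

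Genes of contraction and remodelling changed singly. Tcap, the titin cap protein of the Z-disc, was higher by 0.68 ± 0.07 (adjusted p = 0.00369) and was the 1 of 23 sarcomere genes that passed by either count, with desmin (Des) at -0.15. Among 29 genes of calcium handling and excitation, the inositol trisphosphate receptor Itpr2 was the 1 that passed over all genes (-0.81 ± 0.08, adjusted p = 0.00321), and the kinase Camk2b was higher over the list alone (0.38 ± 0.08). Of 25 hypertrophy and fetal programme genes, the stress-responsive Ankrd1 was higher over all genes (0.54 ± 0.08, adjusted p = 0.0299). Over the list alone, the natriuretic peptide Nppa was also higher (0.68 ± 0.13, adjusted p over all genes = 0.0681) and the calcineurin regulator Rcan1 lower (-0.48 ± 0.13). Of 31 matrix genes, Thbs1, thrombospondin 1, passed by either count and was 4.37-fold higher (2.13 ± 0.13, adjusted p = 0.000425), with Tgfb1 at 0.30. Of 25 genes of the unfolded protein and heat shock responses, the cochaperone Dnajb1 passed by either count and was 3.81-fold higher (1.93 ± 0.22, adjusted p = 0.00669), with the small heat shock protein Hspb7 at -0.35.

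As sets, none of these lists passed in the comparison of all hearts and probe sets with a symbol. The adjusted p was 0.363 for the sarcomere, 0.954 for calcium handling, 0.979 for hypertrophy, 0.0688 for the matrix and 0.954 for the stress responses. The matrix list lay higher on the brighter probe sets (0.0329) and without Ppif-/- heart 2, Ppif-/- heart 3 or WT heart 3 (0.0389, 0.0162 and 0.00858). In the hypertrophy list the median (0.01) lay opposite in sign to the mean (-0.04) and the test, and in the stress response list the mean (0.11) lay opposite to the median (-0.05) and the test. The call of Ankrd1 was lost without each heart but Ppif-/- heart 3 (adjusted p = 0.067 to 0.123).

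Markers of the cell types of the heart shifted by small amounts. Of 12 fibroblast markers, the receptor Pdgfra passed over all genes (-0.44 ± 0.06, adjusted p = 0.0246), and 5 were lower when adjusted over the list alone, among them Pi16 (-0.59 ± 0.13), Gsn (-0.33 ± 0.07) and Dpep1 (-0.46 ± 0.11). Of 12 smooth muscle and pericyte markers, Tagln passed over all genes (-0.51 ± 0.08, adjusted p = 0.0332), and 3 were lower over the list alone, with Myh11 at -0.53 ± 0.11 and Cnn1 at -0.48 ± 0.14, while the pericyte marker Rgs5 was higher (0.27 ± 0.07). Of 12 macrophage markers, the Fc receptor Fcgr3 (0.67 ± 0.07, adjusted p = 0.00399) and the lysosomal Cd68 (0.56 ± 0.09, adjusted p = 0.0394) were higher over all genes. Over that list alone 3 were higher, including Mrc1 (0.27), and 2 lower, including the scavenger receptor Cd163 (-0.53). Of 10 atrial markers, Nppa was higher over the list alone, with Clu at 0.28. The set test called the atrial list higher (adjusted p = 0.0284) and the fibroblast and smooth muscle lists lower (adjusted p = 0.0447 and 0.0131), but none of them with an estimated correlation (adjusted p = 0.365 for each). The atrial call was lost without Ppif-/- heart 1 or WT heart 1 (adjusted p = 0.113 and 0.0836) and the fibroblast call without Ppif-/- heart 2 or 3 or WT heart 1 or 3 (adjusted p = 0.0547 to 0.14). On the brighter probe sets the fibroblast and smooth muscle calls were lost (0.0713 and 0.0516), and the single-gene calls of Pdgfra, Tagln and Cd68 were lost without any 1 heart (adjusted p = 0.0537 to 0.145).

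The remaining cell type lists did not pass as sets. The adjusted p was 0.994 for cardiomyocytes, with Ryr2 at -0.19 and Myl2 at 0.07 and a mean and median of opposite sign, and 0.533 for endothelium, with Egfl7 at 0.22 and Esam at 0.21. It was 0.0891 for macrophages and for granulocytes (Retnlg at -0.31 and S100a9 at -0.40) and 0.128 for lymphocytes (Cd79a and Ms4a1 both at -0.29) and for the erythroid list (Alas2 at 0.38 and Bpgm at 0.10). Macrophages passed on the brighter probe sets (0.0325), with quantile normalisation (0.0487) and without Ppif-/- heart 2 or 3 (0.0352 and 0.048), and granulocytes without Ppif-/- heart 3 (0.048). The adjusted p was 0.786 for adipocytes (Car3 at 0.78 and Retn at -0.17), 0.469 for mesothelium and thymus (Wt1 at 0.28 and Msln at 0.21, and again a mean and median of opposite sign) and 0.0527 for the conduction system and neurons. In the conduction list 2 of 7 markers were lower over the list alone, the neurotrophic factor receptor Gfra3 (-0.46) and the axonal adhesion molecule Cntn2 (-0.53), and the list passed with quantile normalisation (0.0457) and without Ppif-/- heart 2 or 3 (0.0383 and 0.048). In the skeletal muscle list (adjusted p = 0.37), Myl1 was the 1 of 12 markers that passed, and the fast myosin Myh4 was at 0.14.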

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

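Probe sets without a gene symbol in the annotation lay outside the comparison, and 28 of the 12147 passed the adjusted threshold in limma when all 35557 probe sets were tested together, 18 higher and 10 lower in Ppif-/- hearts. This was 0.23% of them, against 103 probe sets or 0.44% of those with a symbol in the same fit. The 2 lower ones with the smallest p were 10367828, with a difference of -5.39, and 10367830, with -2.87, and the 2 higher ones were 10351905, with 2.22, and 10341951, with 1.81. Probe set 10367828 stood at 8.57 in WT and 3.19 in Ppif-/- hearts. What these probe sets read, and whether each reads a transcript at all, was not resolved, and no explanation was tested.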

How the results depend on the processing

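All alternatives but the fit on probe sets with exactly 1 gene symbol (249 probe sets past the threshold) were chosen before the data were examined. The 254 changed probe sets became 160 with the replicate number as a block, 405 on the 11705 brighter probe sets, 131 with all 35557 tested, 453 with a variance trend, 386 with array weights and 131 to 171 without 1 heart. Of the 254, the block kept 146, all probe sets 103, the trend 252, the weights 251 and the fits without 1 heart 121 to 147; the brighter set kept all 202 of them it held. None changed sign in these fits. The fits without 1 heart have fewer arrays and less power; for the other settings the cause was not tested. The looser count stayed within 1.5 times of 396 (278 to 562) and Ppif stayed past the threshold throughout. The 6 pathway lists became 3 with array weights, 0 with an estimated correlation, 2 with fry and 3 to 11 without 1 heart (11 without WT heart 1, 3 without WT heart 2). The 3 cell type lists became 5 with quantile normalisation, 0 with an estimated correlation, 0 with fry and 1 to 5 without 1 heart (5 without Ppif-/- heart 3, 1 without WT heart 1). Same-numbered hearts did not deviate together more than others (r = -0.077, -0.061 and 0.118 across probe sets, other pairs -0.133 to 0.163). This gave no sign of pairing by number, but so few hearts cannot exclude it. With the block, the fibroblast list (adjusted p = 0.0722) and 9 named genes, Pdgfra, Cd68, Tagln, Nqo1, Ankrd1, Ifit2, Nfe2l2, Micu3 and Kdm5d (0.0691 to 0.14), were no longer called. Of 131 named genes, 47 were called. Of these, 35 kept their call in every planned fit on all hearts and 35 in every fit without 1 heart, 6 lost it without any 1 heart (Pdgfra, Cd68, Tagln, Nqo1, Micu3 and Kdm5d), and 0 changed sign; 6 uncalled genes did. With no detection calls, signal over background is unknown for dim probe sets.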

Other observations

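The following called genes lie outside the rule for named genes, were picked singly after their values were seen and were not tested as groups. Kcna4, a voltage-gated potassium channel of the transient outward current, was higher by 0.79 ± 0.12, while the T-type calcium channel Cacna1h (-0.68 ± 0.09), the sodium-activated potassium channel Kcnt2 (-0.59 ± 0.10) and 1 of the probe sets of Kcna2 (-0.48 ± 0.07) were lower. The other Kcna2 probe set differed by -0.26 and did not pass. Ptgds, a prostaglandin D synthase, differed by -1.51 ± 0.16, the endothelial BMP target Tmem100 by -2.38 ± 0.26 and the Z-disc protein Pdlim3 by -1.91 ± 0.25, the last with a wide spread between WT hearts (SD 0.58). Gdpd3, a lysophospholipase D, had the largest increase among probe sets with a gene symbol, 21.7-fold (4.44 ± 0.32), and varied between Ppif-/- hearts (SD 0.73).

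Further genes past the threshold, also picked singly after their values were seen, were Rgs2 (0.78 ± 0.11), a brake on G protein signalling, the protease Adamts1 (1.07 ± 0.14), the endothelial gene Apold1 (0.91 ± 0.15), the kinase Sik1 (0.61 ± 0.09), the chemokine Ccl7 (0.91 ± 0.10) and Phlda1 (1.06 ± 0.18). The cold-inducible RNA-binding protein Rbm3 was higher on all 3 of its probe sets, by 0.66 to 0.67.

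The tests in the paragraphs that follow were chosen after the results were seen, except the counts of changed probe sets and of lists over other splits of the hearts. The 6 hearts can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 254 changed probe sets and the highest of the other splits 0, so 1 of 10 splits gave as many. It gave 6 pathway lists at the preset correlation, where another split gave 8 and 4 of the 10 gave at least 6.

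Called genes lay close together along chromosomes. Of 226 called genes placed in gene order, 68 (30.1%) had another called gene within 5 measured genes, against a median of 26 and at most 58 in 10000 random sets matched on mean level (permutation p = 1e-04, the smallest these can give). Without pairs whose symbols share their first letters, 65 remained, against at most 56, so neighbours with like names do not account for the count. Overlapping or co-regulated neighbours with different names stayed in, so shared probes or shared regulation remain open. Of the 68, 45.6% were lower in Ppif-/- hearts (31 of 68, 95% exact interval 33.5 to 58.1%). This argues against probe mismatches that only lower the signal as the cause of all of them, though not of the lower ones. The other splits, each taking as many genes by smallest p, gave 15 to 40, and the random 95th percentile was 37. The random sets place genes independently, so neighbours that vary together between hearts could also raise the count. Every other split mixes the genotypes, so any clustering tied to genotype would be weaker there, whatever its source. A candidate explanation is chromosome segments that differ between the Ppif-/- and WT mice, such as remaining Sv129 segments or substrain differences. This is a hypothesis that the splits do not test. Among the 20 neighbours of Ppif itself, 0 were called. With 226 of 19854 ordered genes called, so few neighbours could hardly have shown a call, so this count decides nothing. On chromosome 14, which carries Ppif, 3 of 698 ordered genes other than Ppif were called (0.43%), and no run lay there. Genotypes were not analysed here. The 31 runs lay on 15 chromosomes, and the longest held 4 genes (Timm17a, Shisa4, Phlda3 and Lad1, all higher). Several genes named in the results above also lay in runs, among them Hal with Nedd1, Tac1 with Asns, and Bhlhe41 with Itpr2. Mccc1, Cyfip2, Il15, Kcnj11, Micu3, Gas5, Ttc38, 4833420G17Rik, Ifit2 and Nfe2l2 did so as well. So did Btg2, Klf2 and Junb of the immediate early list and Per3 of the clock list. For genes in runs, an effect of Ppif loss and a difference between chromosome segments cannot be told apart here. The same holds for called genes outside runs, since the number of backcrosses and the source of the WT mice were not given.

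Immediate early and clock genes differed together. The fits without 1 heart argue against a single heart as the cause, since the median of the immediate early genes was at least 0.534 in each of them. The 15 clock genes given a textbook phase lay on the sides that a shift in phase needs, Arntl, Clock, Nfil3 and Cry1 negative and 11 genes of the Per and Dbp phase positive. They were sorted into these sides after their values were seen and some did not pass even over the list alone, so the count restates the pattern and does not test it. A shift in clock phase, from the hour of collection or from the mice, stays open. For the immediate early genes, every Ppif-/- heart lay at least 0.595 above every WT heart in the mean of the 25 genes, and handling of the hearts before preservation cannot be told apart from genotype, because no handling times were given and each genotype could have been collected as 1 group.

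Fibroblast and smooth muscle markers lay lower as lists at the preset correlation, but not with an estimated correlation (adjusted p = 0.365 for each), and Pdgfra and Tagln had the smallest p in them. Within the lists the markers moved unequally. The 95% interval of 6 of 12 fibroblast markers lay wholly above the change of Pdgfra, among them Col1a1 (0.21) and Dcn (-0.03), and that of 9 of 12 smooth muscle and pericyte markers above the change of Tagln, with Rgs5 at 0.27. Because both reference genes were picked for their small p, such counts are partly built in and exclude nothing, and a change in the share of either cell type and regulation of these genes within cells stay open. The lists are not independent of the others, as 5 measured fibroblast markers are also in pathway lists.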
